A study of Mus musculus and Homo sapiens with 6 samples.

How the data were processed

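RNA from 6 cell cultures was sequenced. There were 3 mouse cultures of Lys-GFP-ER-HoxA9, a C57Bl/6 line grown with stem cell factor and 0.5 µM beta-estradiol, and 3 human cultures of U937, an established myeloid leukaemia line. Per the labels, each line was represented by a culture given the vehicle DMSO, a culture that had become resistant to the compound C03 and a culture that had become resistant to the compound C07. Per the labels' protocols, compounds were added at 5 µM at the start and up to 50 µM at the end. Each library was made from 250 ng of total RNA with poly-A selection, after ERCC spike-in RNA had been added. Each condition was sampled once per line, so no difference has a replicate check.

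Reads were processed by the authors with TopHat2 2.0.11 and Cuffdiff 2.2.1 on the mm10 and hg19 builds, per the submitters' processing notes. Per the file headers, each deposited table gives FPKM values for a pair of libraries on each line. The same deposited rows give the log2 fold of the second library over the first, a test score, and p-values and q-values of the authors' comparison. The normalization behind the FPKM values and the gene annotation were not given in the sources used here. There were 39175 genes for the mouse line and 63653 for U937. The tables held 0 rows for ERCC spike-ins, so no scaling to them was tried.

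The tables named their libraries only q1, q2 and q3. These names match no sample label, so 0 of the 6 samples could be matched to a library. The libraries are therefore called q1, q2 and q3 of each line throughout, and q1 of the mouse line has no stated relation to q1 of U937. The planned comparisons of each resistant culture with its parental culture, of the C07 with the C03 culture, and the correlations between those comparisons were not run. The statistics planned for them were applied to each of the 3 pairs of libraries of a line. The 3 libraries were treated alike except in how the q3 values were obtained, as given below. The authors' test of a pair compares those libraries, not the conditions.

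For libraries q1 and q2 the authors' FPKM was read directly, and for q3 it was computed from the first library's FPKM and the authors' deposited log2 fold. The other per-library value column of each table was left unused, 2 columns in all. This left 575 mouse genes and 1216 human genes without a q3 value. They were listed at 0 in both q1 and q2, where a fold cannot give the value of q3. Genes found only in q3 are thus missing from its gene numbers, 2-fold counts and FPKM sums. Genes found only in q1 or only in q2 were kept, so the q3 numbers can be too low beside the others. Ratios were computed as log2 of the FPKM plus a pseudocount of 1, which understates the ratio of weakly expressed genes. Genes listed at 0 in 1 library of a pair entered the 2-fold counts and the medians through the pseudocount. They made up 65, 52 and 44 of the genes counted at 2-fold in the mouse pairs q1 with q2, q1 with q3 and q2 with q3, and 87, 67 and 41 in the U937 pairs. Genes entered a pair where Cuffdiff gave them the status OK, and genes with a locus under 300 bp or a short non-coding RNA symbol were left out. With 1 library per condition no test of its own was made across genes, and genes past a fixed size of 2-fold were counted. Read depth is unknown because the tables hold no counts, so no counting interval could be given.

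Gene lists, 35 in all, were fixed before the data were examined. Members needed a mean FPKM of at least 1 over the pair. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called apart when it lay outside the central 95% of them. This describes the libraries and is not a test of conditions. Neighbouring genes were scanned with a running median over 11 genes, beside the extremes of 1000 shuffles of gene order. Windows beyond those extremes were joined into 1 stretch where they started at most 11 genes apart. A stretch can therefore hold windows that did not exceed the shuffles. Genes within 1 Mb of DHODH were taken as its neighbours. Loci are those of the tables. Cuffdiff gave overlapping genes a shared locus, and the values of overlapping genes, paralogs and pseudogenes are uncertain because reads can be divided among them. No strand information was given, so antisense partners cannot be separated.

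The rule for named genes was fixed before the data were examined, for comparisons with parental cells, and was applied to pairs of libraries. It took DHODH, its neighbours, up to 4 members of each list by size of ratio, and for each pair the 10 genes with the largest ratio each way among those with at least 5 FPKM in at least 1 of the pair. After the values were seen, genes listed at 0 in either library of the pair and small RNA classes inside longer loci were also left out of those 10. Mouse gene classes came from GENCODE M21, which held 37691 of the mouse gene identifiers. XIST, TSIX and chromosome Y genes were not named in U937.

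A set of unchanged libraries was simulated 100 times per line with the standard error that the authors' fold and test score imply for each gene. The counting, list and scan steps were tested on simulated data in which 200 genes, a stretch of 30 neighbouring genes and a list of 20 genes had been changed. The noise put in had a standard deviation of 0.15 on the log2 scale per library, while the authors' scores imply a median standard error of 0.39 for the ratio of a mouse pair and 0.45 for that of a U937 pair, so the noise put in was smaller also for a ratio. These checks therefore test the code, not the error of the 2-fold counts. Recovery was counted among genes at 5 FPKM or more. In the simulated mouse pair, 32 of 33 genes raised by 1.5 on the log2 scale and all 38 genes raised by 3 were recovered at 2-fold. In the simulated U937 pair, 37 of 37 genes raised by 1.5 and 37 of 37 raised by 3 were recovered, and the inserted stretch was found in both lines. Of genes lowered by 1.5, 42 of 45 and 36 of 39 were recovered, and 0 unchanged genes were counted. The alternatives varied the pseudocount, the filter, the status, the scaling, the short genes, the neighbour window and the call. Others, chosen after the data were seen, left out other contigs, genes listed at 0 or the chromosome that holds DHODH. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.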

Results

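Transcript levels were measured by poly-A RNA sequencing in a mouse line and a human line, each as a parental culture and as cultures with acquired resistance to compounds C03 and C07. Lys-GFP-ER-HoxA9 is a mouse myeloid line carried by an estrogen-dependent HOXA9 fusion, and U937 is a human myeloid leukaemia line. Each line had 3 libraries, 1 per condition, named q1, q2 and q3 in the deposited tables with no link to a condition. The study asked which transcripts differ between resistant and parental cells. Because the libraries could not be matched to conditions, the values of each library and the differences between pairs of libraries are given, and no direction of resistance is drawn from them. In the mouse libraries 11336, 11299 and 11420 genes reached 1 FPKM in q1, q2 and q3, and in the U937 libraries 12713, 12834 and 12755 did. The q3 numbers leave out genes found only in q3. Mitochondrial genome transcripts held 4.11%, 5.65% and 5.14% of the summed FPKM in the mouse libraries and 8.49%, 11.6% and 11.9% in the U937 libraries.

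DHODH, the mitochondrial enzyme that oxidises dihydroorotate in de novo pyrimidine synthesis, was among the most divergent transcripts of both lines. In the mouse line Dhodh (ENSMUSG00000031730, chromosome 8, 109591343 to 109608673, mm10) was measured at 21.2 FPKM in q1, 464 in q2 and 266 in q3. In U937 DHODH (ENSG00000102967, chromosome 16, 72042487 to 72058954, hg19) was measured at 12.6 FPKM in q1, 166 in q2 and 150 in q3. The mouse log2 ratio was 4.39 for q2 over q1 and 3.59 for q3 over q1, and for q3 over q2 it was -0.80. In U937 these ratios for DHODH were 3.62, 3.48 and -0.14. The standard error implied by the authors' fold and score was 0.40, 0.38 and 0.36 for the mouse pairs and 0.34, 0.35 and 0.32 for the U937 pairs. In the authors' deposited table Dhodh had q = 0.00834 for both mouse pairs with q1 and q = 0.566 for q2 with q3. The lowest q of any gene in that table was 0.00834 in each mouse pair and 0.0101 in each U937 pair. Many genes share these lowest values, which therefore do not rank genes. The authors' deposited table gave U937 DHODH q = 0.0101 for both pairs with q1 and q = 1.0 for q2 with q3. The other members of the de novo pyrimidine pathway spanned less, and the list of all 3 had medians from 0.05 to 0.23 in U937 and from -0.08 to 0.27 in the mouse line, none outside the random lists. CAD, which starts the pathway, was at 42.1, 27.5 and 36.7 FPKM in U937, and mouse Cad was at 40.3, 43.0 and 45.6. UMPS, which ends it, was at 24.1, 25.1 and 28.5 FPKM in U937, and mouse Umps was at 36.4, 44.1 and 41.8.

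Genes beside DHODH also differed between the libraries, but not all with its profile. Mouse Dhx38, Txnl4b, Hp and Ist1 were lower in q3 than in q2, as Dhodh was, while Atxn1l, Ap1g1, Gm17344, Phlpp2 and Cmtr2 were higher. Of the 13 measured mouse neighbours within 1 Mb, 6 were at least 2-fold higher in q2 than in q1, 13 were higher in q3 than in q1, and 7 were higher and 1 lower in q3 than in q2. The mouse neighbours had median log2 ratios of 0.73, 3.16 and 1.24 for q2 over q1, q3 over q1 and q3 over q2. Of the U937 neighbours, 12 of 16 were at least 2-fold higher in q2 than in q1, 20 of 20 in q3 than in q1, and 13 of 22 in q3 than in q2, with 0 lower. Their median log2 ratios were 1.91, 3.44 and 1.36. All 6 medians lay above each random list drawn. Random lists draw genes independently, while neighbours can share a locus and move together. Among all runs of as many neighbouring genes, those as high numbered 41 of 11043, 5 of 11112 and 16 of 11081 in the mouse pairs. In the U937 pairs they numbered 15 of 12355, 30 of 12232 and 33 of 12249. These runs overlap and include those near DHODH. The mouse median for q3 over q2 turned to -0.19 with a window of 2 Mb.

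Dhx38, a splicing helicase, was at 19.2, 351 and 220 FPKM in mouse libraries q1, q2 and q3, and Txnl4b at 5.43, 118 and 73.0. Hp, the haemoglobin-binding plasma protein haptoglobin, was at 6.14, 191 and 49.0, and Ist1, of the membrane-scission machinery, at 33.6, 590 and 365. From Zfp821 onward, farther from Dhodh on the side of Ist1, the neighbours within 1 Mb were highest in q3. Ap1g1 (ENSMUSG00000031731 and an overlapping entry of the same symbol) was at 22.3, 37.6 and 263 FPKM in the first entry, and Atxn1l was at 7.36, 11.2 and 74.5. Zfp821, Gm17344, Phlpp2 and Cmtr2 were highest in q3 too, as was Zfhx3 on the far side of Dhx38, and Pkd1l3, in the locus of Ist1, was at 0.313, 4.31 and 3.43. In U937, DHX38 was at 26.1, 679 and 367 FPKM, TXNL4B at 11.7, 271 and 164, PMFBP1 at 8.17, 185 and 104, and HP at 0.574, 18.7 and 13.5. AP1G1, a clathrin adaptor subunit, was at 22.0, 88.1 and 492 FPKM in U937, IST1 at 92.7, 352 and 1972 and ATXN1L at 5.52, 23.6 and 127. U937 DHX38, HP, PMFBP1, RP11-384M15.3 and TXNL4B share a locus in the table, as do IST1, ATXN1L and ZNF821, so their separate values are uncertain. In the authors' deposited table Dhx38, Txnl4b, Hp and Ist1 had q = 0.00834 and DHX38, AP1G1 and IST1 q = 0.0101 for both pairs with q1, and TXNL4B had q = 0.0396 and 0.0185. ATXN1L was called only for q1 with q3 (q = 0.0335). The authors' deposited table did not call HP (q = 0.367 and 0.593), PMFBP1, RP11-384M15.3 or mouse Pkd1l3 for either pair with q1.

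**Figure D1:**
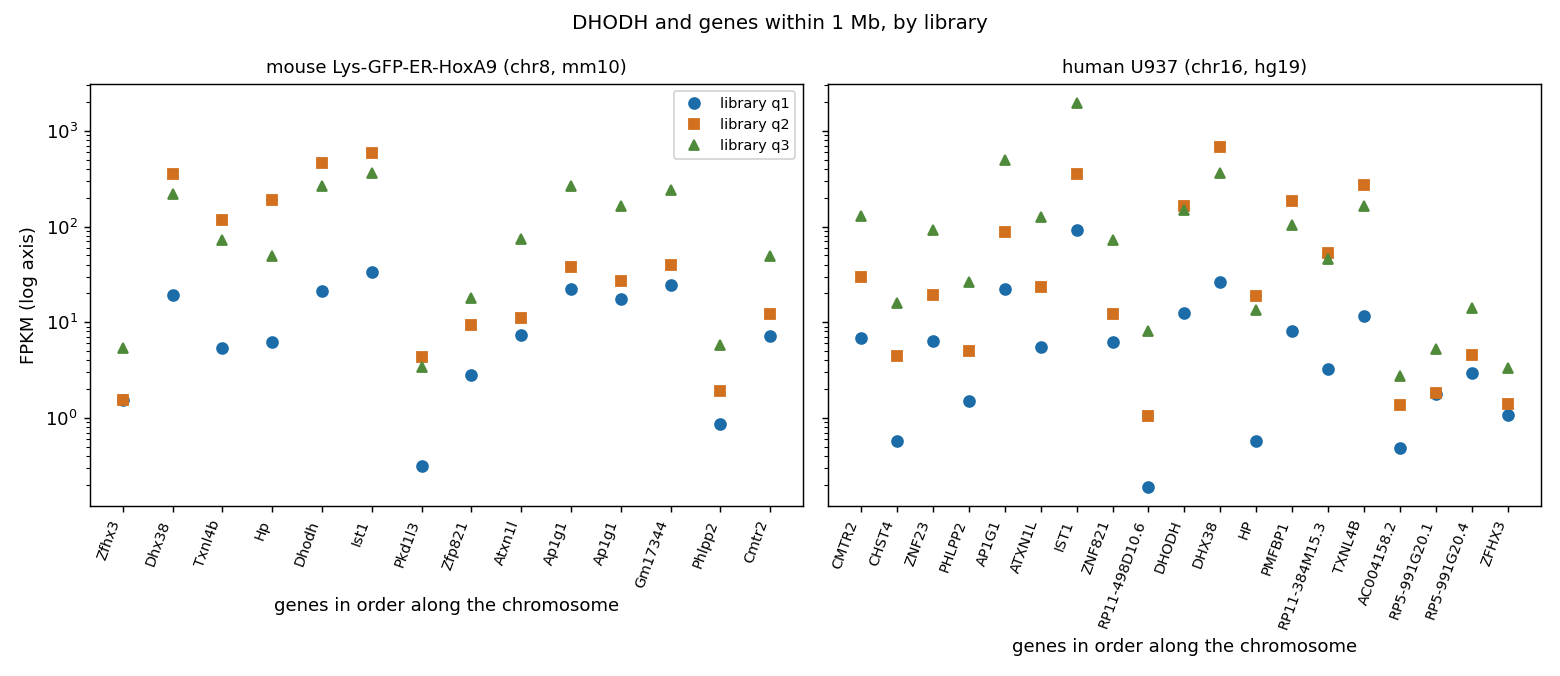
FPKM on a log axis of DHODH and the genes within 1 Mb of it, in order along mouse chromosome 8 and human chromosome 16, with 1 point per library (circle q1, square q2, triangle q3) and genes listed at 0 in a library left out. Dhodh lies at 21.2, 464 and 266 FPKM in the mouse libraries and DHODH at 12.6, 166 and 150 in U937, and q1 is the lowest point of each gene drawn.

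The scan along the chromosomes placed these genes in longer stretches. For mouse q2 over q1 windows above each shuffle of gene order, joined across gaps, ran along chromosome 8 from 106168875 to 116960445. The 67 genes there had a median log2 ratio of 1.40, and 52.2% of them were at least 2-fold higher. A smaller stretch ran from 79266424 to 82774160, in the part before 105900441, where genes as a whole had a median of 0.44. For mouse q3 over q1 the stretch ran from 105900441 to 116993537, with a median of 1.75 over 75 genes and 81.3% of them at least 2-fold higher. For mouse q3 over q2 it ran from 105900441 to 110972480, with a median of 1.07 over 49 genes. Kars, Aars, Sf3b3, Cfdp1, Vac14 and Gabarapl2 were within the mouse stretches for q2 over q1 and q3 over q1. Aars, Cfdp1 and Gabarapl2 lay beyond the end of the stretch for q3 over q2. Aars, the alanyl-tRNA synthetase, was at 61.9, 262 and 256 FPKM and Cfdp1 at 74.5, 439 and 307.

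In U937 the stretch for q2 over q1 covered chromosome 16 from 58163433 to 74483790, with a median log2 ratio of 1.73 over 141 genes and 78.0% of them at least 2-fold higher. For q3 over q1 it covered 53467889 to 79246564, with a median of 0.95 over 202 genes, and 31724550 to 50405391, with a median of 0.79 over 21 genes. For q3 over q2 the scan was higher from 69740899 to 77776897, with a median of 1.34 over 79 genes, and from 31482906 to 56554195, with a median of 0.83 over 41 genes. It was lower from 58265061 to 70099851, with a median of -0.86 over 100 genes. GOT2, the mitochondrial aspartate aminotransferase, was at 88.1, 532 and 139 FPKM, and AARS at 81.1, 316 and 1628. Outside chromosome 16, U937 q3 over q2 was lower on chromosome 10 from 105995114 to 119134978, with a median of -0.56 over 31 genes. Outside chromosome 8, mouse q3 over q2 was higher on chromosome 13 from 21721442 to 24814013, which holds a histone cluster, with a median of 0.89 over 25 genes. A mouse window on chromosome 8, 60890418 to 67502580, was lower in q3 than in q2 with a median of -0.67. All of chromosome 8 before 105900441 had a median of -0.44 for this pair, so the window lay on a broader shift.

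**Figure D2:**
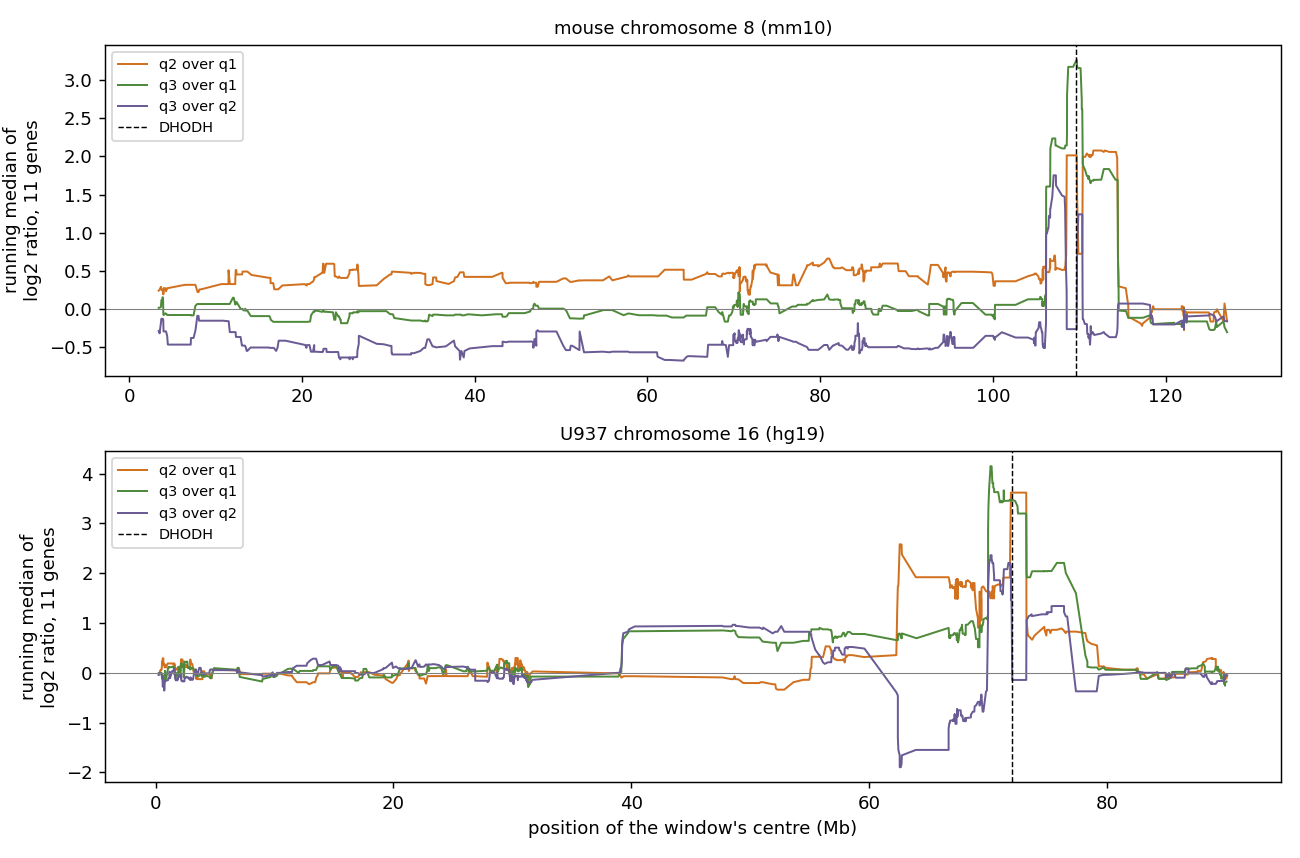
Running median over 11 genes of the log2 ratio of each pair of libraries against position in Mb on mouse chromosome 8 and U937 chromosome 16, with DHODH at the dashed line. The highest windows reach 3.27 for mouse q3 over q1 and 4.15 for U937 q3 over q1, and the levels change in steps along both chromosomes.

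Across all genes of the mouse line, 253 of 13226 genes were at least 2-fold apart between q1 and q2, with 118 higher in q2. Between q1 and q3, 276 of 13363 were apart with 192 higher in q3, and between q2 and q3, 331 of 13364 were apart with 240 higher in q3. In U937, 423 of 15001 genes were apart between q1 and q2 with 319 higher in q2, 309 of 14983 between q1 and q3 with 216 higher in q3, and 254 of 14910 between q2 and q3 with 116 higher in q3. The correlation of log2 values across genes, which are not independent replicates, was between 0.973 and 0.978 for the mouse pairs and between 0.972 and 0.984 for the U937 pairs. The authors' deposited table called 79, 110 and 124 genes in the mouse pairs q1 with q2, q1 with q3 and q2 with q3, and 132, 93 and 73 genes in the U937 pairs. Of these calls 48, 92 and 89 in the mouse pairs and 125, 85 and 36 in the U937 pairs were higher in the second library, so for mouse q1 with q2 the balance was opposite to that of the 2-fold counts. Libraries simulated as unchanged, with the error that the authors' scores imply, gave on average 792 of 12830 mouse genes and 1437 of 14215 U937 genes past 2-fold, more than any observed pair. That error is thus larger than the spread between these libraries and gives no background for the 2-fold counts. A pseudocount of 0.1 gave 830 to 1043 mouse genes and 945 to 1448 U937 genes per pair.

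Of the 10 mouse genes with the largest ratio of q2 over q1, 8 lay on chromosome 8: Hp, Dhodh, Txnl4b, Dhx38, Ist1, Cfdp1, Vac14 and Sf3b3. The other 2 were Gm16042 and Prg2, the eosinophil major basic protein gene, at 4.40, 57.1 and 35.4 FPKM in q1, q2 and q3. The 10 lower in q2 were Rps12-ps3, another Gm16042 entry, Ptprf, Ephb2, Crip1, Ecm1, Mzb1, Gm1821, Rps24-ps3 and Ccr2. Ptprf, a receptor tyrosine phosphatase, was at 14.5, 1.56 and 17.3 FPKM, and the chemokine receptor gene Ccr2 at 172, 44.0 and 289. Pseudogene values such as Rps12-ps3 are uncertain because reads are shared with the parent gene. The authors' deposited table called all of these 20 entries but the Gm16042 entries, Rps12-ps3, Gm1821 and Rps24-ps3.

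For mouse q3 over q1 the 10 highest were Clu, Dhodh, Txnl4b, both Ap1g1 entries, Dhx38, Ist1, Slc35d3, Gm17344 and Atxn1l. Clu, which encodes the secreted chaperone clusterin, was at 6.62, 3.88 and 116 FPKM, and Slc35d3 at 1.02, 1.22 and 18.5. Lower in q3 than in q1 were Gm16042, Rps24-ps3, Mzb1, Gm13736, Gm27038, Mras, Lcn2, G0s2, D1Ertd622e and Gm20400. Lcn2, the neutrophil granule gene lipocalin 2, was at 70.9, 26.0 and 23.2 FPKM. In the authors' deposited table the higher genes were called except Gm17344 and the second Ap1g1 entry, and of the lower genes only Mzb1, Lcn2 and D1Ertd622e were. For q3 over q2 the highest were Rps12-ps3, Clu, Slc35d3, Gm25733, Ptprf, Ap1g1, Lama5, Ccr2, Atxn1l and Lcp2, and the lowest were Ms4a3, Elane, Gda, Rgs10, Hp, Mtus1, Gpr128, Prg3, Tgfbi and F630028O10Rik. Elane, which encodes neutrophil elastase, was at 6.36, 18.0 and 3.36 FPKM, and Ms4a3 at 12.1, 27.6 and 5.14. The authors' deposited table called all of these for q2 with q3 but Rps12-ps3, Gm25733 and Rgs10.

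Of the 10 U937 genes with the largest ratio of q2 over q1, 7 were on chromosome 16: DHX38, TXNL4B, PMFBP1, RP11-384M15.3, HP, DHODH and CMTM1. The rest were FABP4, a fatty-acid binding protein gene at 0.382, 19.9 and 4.80 FPKM, CREB3L3 at 0.975, 22.8 and 7.92, and the monocyte chemokine gene CCL2 at 8.75, 110 and 61.7. Genes lower in q2 included Z82188.1, RP11-578F21.10, DIAPH2, LUZP6, AC018867.2, PDIA3P2, DET1 and CEACAM6. Of all these genes the authors' deposited table called DHX38, TXNL4B, DHODH, CREB3L3, CCL2 and CEACAM6 for q1 with q2, and not FABP4 or the others.

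All 10 U937 genes with the largest ratio of q3 over q1 were on chromosome 16: RP11-529K1.3, DDX19B, AP1G1, IST1, EXOSC6, AARS, VAC14, ATXN1L, RP11-296I10.3 and RP11-296I10.6. DDX19B, an RNA helicase, was at 7.39, 5.87 and 221 FPKM. Genes lower in q3 than in q1 included RP11-578F21.10, DNAJC25-GNG10, AC018867.2, AC011933.1, CD48, AC019206.1, PDIA3P2 and TGIF2-C20orf24, with CD48, a lymphocyte and monocyte surface protein gene, at 13.4, 8.62 and 3.00 FPKM. In the authors' deposited table the higher genes were called except RP11-529K1.3, and of the lower genes named only CD48 was. For q3 over q2 the highest were DDX19B, Z82188.1, RP11-529K1.3, B3GNT8, DIAPH2, HINT1, RP11-49C24.1, RP11-296I10.3, IST1 and ZNF821, with HINT1 at 183, 144 and 1054 FPKM. The lowest were XAGE1B, ZNF888, CMTM1, CKLF-CMTM1, RP11-410D17.2, SLC12A4, WWOX, SLC38A7, PLEKHG4 and LCAT, and of these CMTM1 was at 4.38, 62.4 and 12.1 FPKM. For q2 with q3 the authors' deposited table called only DDX19B, RP11-49C24.1, SLC12A4, WWOX, SLC38A7 and PLEKHG4 of these 20, and not HINT1 or CMTM1.

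Lists of myeloid differentiation genes had medians outside the random lists in both lines, with few members at 2-fold. Over all lists 38 of 102 mouse medians and 37 of 99 U937 medians lay outside, so lying outside was not particular to these lists. Random lists draw genes independently, while members of a list may vary together. The ratio of a gene in the third pair also follows from its other 2 ratios. In U937 the mature neutrophil list had median log2 ratios of 0.71, 0.43 and -0.22 for q2 over q1, q3 over q1 and q3 over q2, all outside the central 95% of random lists, the last not when 5 FPKM was required in a library, and 3, 1 and 0 of 8 members were at 2-fold. CYBB, the phagocyte oxidase subunit, was at 3.07, 21.6 and 20.7 FPKM, and the calcium-binding protein gene S100A8 at 3.39, 10.0 and 6.44. The U937 monocyte and macrophage list had medians of 0.41, 0.29 and -0.12, with only the first and second outside and 3 of 13, 1 of 11 and 1 of 12 members at 2-fold. The integrin gene ITGAX was at 3.97, 11.7 and 6.14 FPKM and the macrophage growth factor receptor gene CSF1R at 0.687, 2.87 and 2.03. The primary granule list had medians of -0.25, 0.11 and 0.29, all outside, the second neither with a pseudocount of 5 nor with 5 FPKM required. Of its 10 members 2, 0 and 1 were at 2-fold, with PRTN3 at 74.8, 30.6 and 99.3 FPKM and ELANE at 501, 210 and 350. In the mouse line the mature neutrophil list had medians of 0.81, -0.25 and -0.51, the first and last outside. The second was outside too at -0.32 with a pseudocount of 0.1 and at -0.84 with 5 FPKM required. Of its 5 members, 1 was 2-fold higher and 1 lower in q2 than in q1 and likewise in q3 than in q1. These were Cebpe, at 11.8, 34.3 and 33.0 FPKM, and Lcn2, at 70.9, 26.0 and 23.2. Another member was 2-fold lower in q3 than in q2. The mouse primary granule list had medians of 0.06, -0.34 and -0.52, the last 2 outside, with 2, 1 and 2 of 7 members at 2-fold. The mouse monocyte list had medians of -0.03, 0.50 and 0.34, the last 2 outside, with 1 of 11, 2 of 10 and 1 of 11 members at 2-fold. With 5 FPKM required in a library the second turned to -0.06 and the first was -0.54 and outside.

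In the mouse line the eosinophil list of 3 genes had medians of 2.11, 0.44 and -0.67 for q2 over q1, q3 over q1 and q3 over q2, all outside, with 2, 1 and 1 members at 2-fold, carried by Prg2 and by Prg3 at 11.4, 52.5 and 15.8 FPKM. The mast cell and basophil list had medians of 0.90, 0.40 and 0.05, the first 2 outside the random lists, with 2 higher and 1 lower of 4 members, 1 higher of 4 and 1 lower of 5 at 2-fold. Cpa3, a mast cell protease gene, was at 113, 306 and 148 FPKM and Hdc at 1.60, 11.1 and 7.22, while Mcpt8 was at 57.6, 24.2 and 33.9. The megakaryocyte list had medians of 0.31, 1.35 and 0.17, the second outside, and 0 of 3, 2 of 3 and 2 of 5 members at 2-fold, with Pf4 at 4.65, 8.36 and 18.9 FPKM and Gp9 at 8.11, 6.15 and 22.1. The third was 1.09 and outside with 5 FPKM required, and the first was 0.23 and outside with a pseudocount of 5. The B-cell list had medians of -0.14, 0.34 and 0.75, the last 2 outside, and 0, 1 and 2 of 5 members at 2-fold, with Vpreb3 at 6.78, 6.04 and 38.7 FPKM. The second was 0.14 and not outside with a pseudocount of 5.

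Mitochondrial genome mRNAs, all of which code for respiratory chain or ATP synthase subunits, had median log2 ratios of 0.30, 0.28 and 0.01 in the mouse line and 0.48, 0.51 and -0.01 in U937 for the pairs in the same order. In each line the first 2 lay above every random list, and 0 members reached 2-fold. Random lists were matched on expression only in 20 bins and drew genes independently. This position therefore does not measure how unusual a joint shift of these mRNAs is. MT-ND4 was at 5759 FPKM in U937 q1, 9073 in q2 and 8502 in q3, and mouse mt-Atp6 was at 3340, 5322 and 4202. Nuclear oxidative phosphorylation genes had medians from -0.14 to 0.04 in U937, outside the random lists for q2 over q1 and q3 over q2, and from -0.02 to 0.03 in the mouse line, with 0 outside. Mouse histone mRNAs had medians of -0.97, 0.49 and 1.37, all outside. At 2-fold 7 of 14 were lower in q2 than in q1, 3 of 20 higher in q3 than in q1 and 13 of 16 higher in q3 than in q2. Hist1h2bj was at 4.37, 1.27 and 11.1 FPKM and Hist1h2bc at 22.2, 9.20 and 19.4. In U937 histone mRNAs had medians of 0.31, 0.33 and 0.14, the second outside, and the first was also outside with a pseudocount of 5, at 0.23.

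The cholesterol synthesis list had medians of 0.50, 0.26 and -0.30 in U937, all outside the random lists, with 1 of 19 members at 2-fold for q2 over q1 and 0 for the other pairs, with HMGCS1 at 129, 245 and 173 FPKM and MVD at 39.1, 99.0 and 65.7. Its mouse medians were -0.19, -0.10 and 0.06, the first 2 outside. Glycolysis genes had medians of -0.08, -0.21 and -0.26 in U937, the last 2 outside, with GAPDH at 3793, 3091 and 2575 FPKM, and mouse medians ran from -0.10 to 0.03. The mouse -0.10, for q3 over q2, was outside, but not with 5 FPKM required or with short RNA genes kept. Pyrimidine salvage genes had medians from -0.02 to 0.16 in U937. The median of 0.16, for q2 over q1, was outside, but not with 5 FPKM required. Among them UPP1, a uridine phosphorylase, was at 3.10, 10.1 and 6.08 FPKM and TK2, on chromosome 16, at 3.31, 24.7 and 7.78. Their mouse medians lay from -0.04 to 0.01, with 0 members at 2-fold. The drug efflux transporters had medians from -0.14 to -0.01 in U937 and from -0.02 to 0.10 in the mouse line, and nucleoside transporters from -0.09 to 0.14 and from -0.19 to -0.03, with 0 lists outside and 0 members at 2-fold. NRF2 targets had medians from -0.11 to 0.18 in U937, where NQO1, on chromosome 16, had log2 ratios of 2.33, 0.81 and -1.51, and from -0.16 to 0.27 in the mouse line. The U937 0.18, for q2 over q1, and the mouse 0.27 and -0.16, for q2 over q1 and q3 over q2, were outside, and U937 q3 over q1 was outside only with short RNA genes kept. Amino acid response genes had medians from -0.06 to 0.03 in U937 and 0.00 to 0.10 in the mouse line, and the members at 2-fold were AARS and Aars, of the stretches above.

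**Figure D3:**
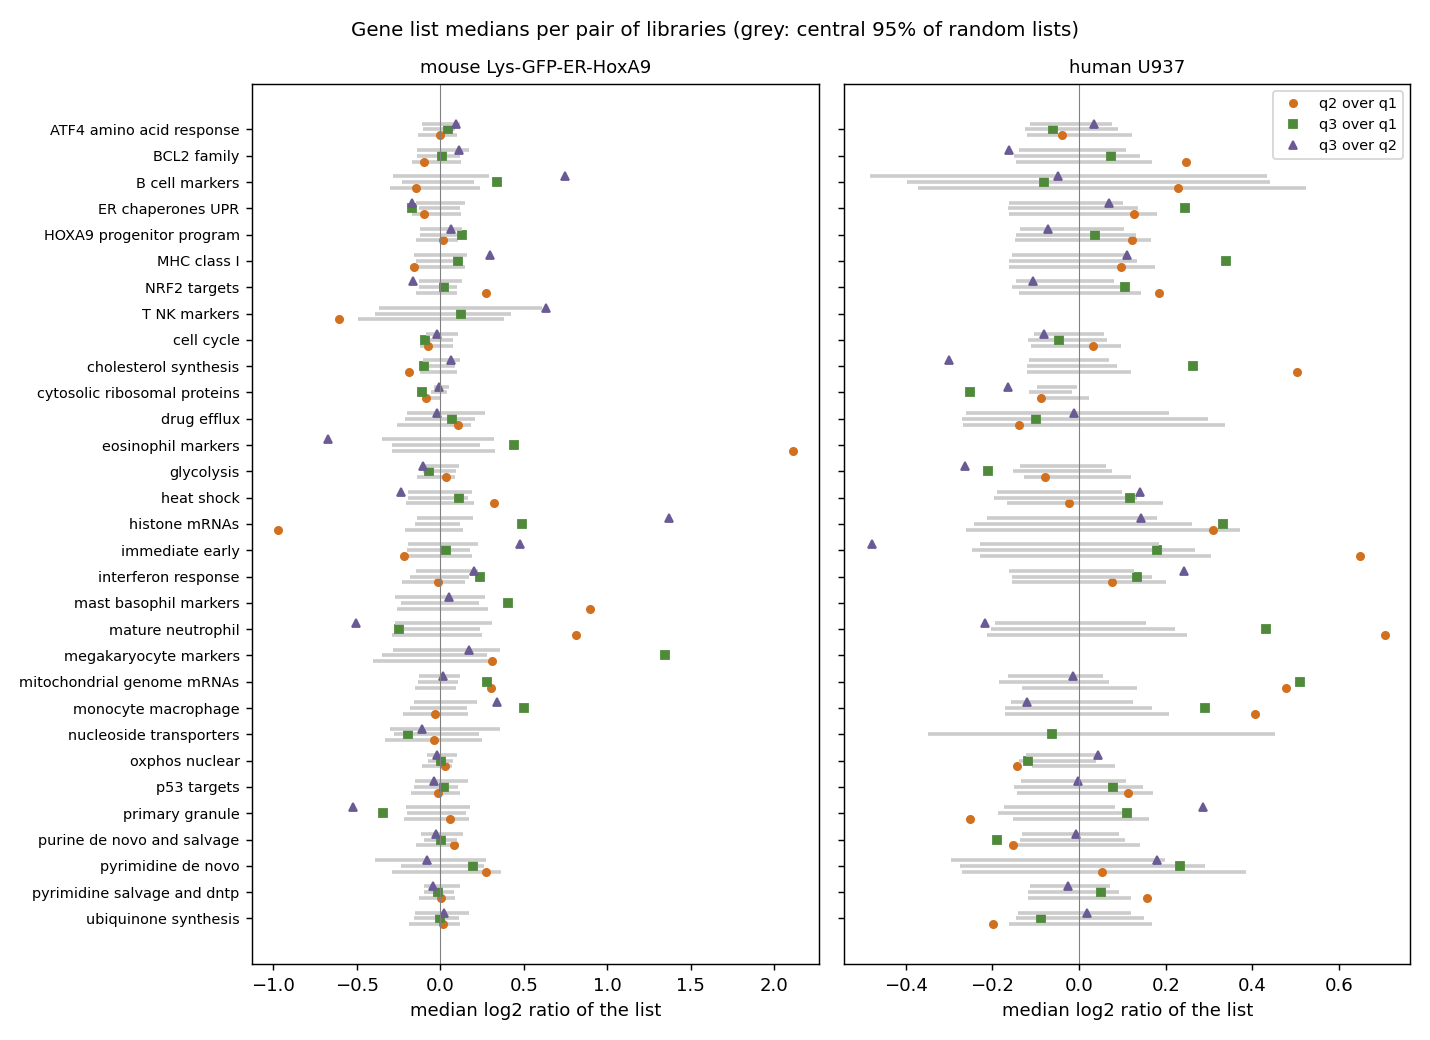
Median log2 ratio of each fixed gene list with at least 3 measured members, for each pair of libraries (circle q2 over q1, square q3 over q1, triangle q3 over q2) in the mouse line and in U937, with the central 95% of matched random lists as grey bars. The mouse eosinophil list reaches 2.11 and the mouse histone list runs from -0.97 to 1.37.

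Genes that spanned at least 2-fold over the 3 libraries in both lines were mostly on the chromosomes that hold DHODH. Of 8795 symbols measured in both lines, 205 spanned 2-fold in the mouse libraries and 203 in the U937 libraries, and 62 did so in both, where independent lists would share 4.73. At 8-fold 7 were shared and independent lists would share 0.0191. All 7 were DHODH or its neighbours within 1 Mb in both lines. Both expected numbers treat genes as independent, which neighbours that move together are not, so the shared genes are not separate coincidences. Of the 62, 51 lay on mouse chromosome 8 and human chromosome 16. They included TXNL4B, DHX38, IST1, HP, DHODH, AP1G1, ATXN1L, VAC14, CMTR2, PDF, SF3B3, GABARAPL2, DDX19A, KARS and PDPR. With both chromosomes left out 10 genes were shared, which also drops NUPR1, on human chromosome 16 and mouse chromosome 7. No expected number was computed for that setting. The remaining genes, on other chromosomes, included CCL3, ELANE, CD52 and CDKN1A, chosen after their values were seen, with mouse Cdkn1a at 53.2, 26.5 and 57.2 FPKM and U937 CDKN1A at 9.76, 22.3 and 13.5.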

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

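No planned comparison of resistant with parental cultures could be run, because the libraries carry no condition, so each alternative fixed beforehand was applied to pairs of libraries. No paired analysis was possible because the library names carry no replicate numbers and each condition was sampled once. Alternatives without the chromosome that holds DHODH, without other contigs and without genes listed at 0 were chosen after the data were seen. The pair and single-library counts depended on the treatment of weakly expressed genes, and the cause was not tested further. With a pseudocount of 0.1 the mouse pairs q1 with q2, q1 with q3 and q2 with q3 had 830, 919 and 1043 genes at 2-fold and the U937 pairs 1448, 1245 and 945. With a pseudocount of 5 they had 116, 120 and 121, and 165, 114 and 96. Requiring 5 FPKM tests fewer genes, and left 182 and 216 in the mouse pairs with q3 and 253, 173 and 158 in the U937 pairs. The authors' own call gave 79, 110 and 124, and 132, 93 and 73. Without chromosome 16 the U937 pairs with q3 had 198 and 144. Median centring, upper quartile scaling, kept short genes and dropped genes at 0 held each pair total within 1.5 times, and adding NOTEST genes or leaving out other contigs changed none. Totals of genes higher and lower were chosen as the count to follow only after the alternatives had been fixed by direction. Of the 120 counts by direction, 40 moved by over 1.5 times.

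Genes apart from both other libraries numbered 76, 67 and 113 in mouse q1, q2 and q3 and 132, 80 and 86 in U937. Libraries simulated as unchanged with the error the authors' scores imply gave on average 341 and 630 per library, more than any of these, so that error overstates the spread and gives no background for them. A pseudocount of 0.1 gave 210, 252 and 296, and 418, 254 and 218. A pseudocount of 5 gave 45, 19 and 44, and 58, 35 and 49. Leaving out the chromosome that holds DHODH gave 40 in mouse q1 and 73, 45 and 27 in U937. The 62 genes spanning 2-fold in both lines became 118 with a pseudocount of 0.1 and 10 without those chromosomes.

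The DHODH ratios moved by less than the implied standard error in each alternative run. The medians of its neighbours moved with the window. Mouse q2 over q1 gave 1.45 within 0.5 Mb and 1.99 within 2 Mb, mouse q3 over q1 gave 1.91 within 2 Mb, and mouse q3 over q2 gave 0.85 within 0.5 Mb and turned to -0.19 within 2 Mb. U937 q2 over q1 and q3 over q2 gave 1.69 and 1.85 within 2 Mb. With a pseudocount of 0.1 the neighbour medians were 1.04, 3.22 and 1.58 in the mouse pairs and 2.03, 3.94 and 1.71 in U937. With 5 they were 0.64, 2.68 and 0.66, and 1.5, 2.45 and 0.58. Requiring 5 FPKM gave 1.09 for mouse q2 over q1 and 1.86 for U937 q3 over q2. Over all alternatives, list medians left the range outside the random lists 11 times and entered it 13 times, and mouse q3 over q1 of the monocyte list turned to -0.060 when 5 FPKM was required, which leaves fewer members. Read depth is not given in the tables, so its limit on weak genes could not be computed.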

Other observations

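The tests on overlapping loci and on the cell cycle list were chosen only after the result was seen, and so was each pattern. The cell cycle test replaced a first version on the list median, seen at -0.02, because a median over all phases decides little. No biological explanation by condition was tested, because the libraries carry none.

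The medians of some chromosomes differed between libraries. On mouse chromosome 13 the median log2 ratio was -0.38 for q3 over q1 and -0.35 for q3 over q2, against -0.03 for q2 over q1. Mouse chromosome 8 before position 105900441 had medians of 0.44, 0.01 and -0.44 over q2 over q1, q3 over q1 and q3 over q2, and after 116993537 medians of -0.05, -0.18 and -0.13. Mouse chromosome 11 had medians of 0.18, 0.01 and -0.17. U937 chromosome 22 had medians of 0.26, 0.34 and -0.01. Mouse chromosome 11 and U937 chromosome 22 were not split along their length, so their medians may come from part of the chromosome. The values of library q1 stood apart from q2 and q3 for DHODH in both lines (21.2 against 464 and 266, and 12.6 against 166 and 150). These values were not used to assign a condition to q1, which stays unknown.

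For the remaining fixed lists, over the 3 pairs in U937 and then the mouse line, cell cycle genes ran from -0.08 to 0.03 and from -0.09 to -0.02, cytosolic ribosomal proteins from -0.25 to -0.09 and from -0.11 to -0.01, and purine genes from -0.19 to -0.01 and from -0.03 to 0.08. Ubiquinone synthesis genes ran from -0.20 to 0.02 and from 0.00 to 0.02, p53 targets from 0.00 to 0.11 and from -0.04 to 0.02, and BCL2 family genes from -0.16 to 0.25 and from -0.10 to 0.12. ER chaperones ran from 0.07 to 0.25 and from -0.17 to -0.10, heat shock genes from -0.02 to 0.14 and from -0.23 to 0.32, and interferon genes from 0.08 to 0.24 and from -0.01 to 0.24. MHC class I genes ran from 0.10 to 0.34 and from -0.16 to 0.30, MHC class II genes from -0.26 to -0.02 and from -0.30 to 0.60, and immediate early genes from -0.48 to 0.65 and from -0.22 to 0.48. In that order, the medians outside the random lists numbered 0 and 1 for cell cycle genes, 3 and 2 for ribosomal proteins, 2 and 0 for purine genes, 1 and 0 for ubiquinone genes, 0 and 0 for p53 targets, 2 and 0 for BCL2 family genes, 1 and 2 for ER chaperones, 1 and 2 for heat shock genes, 1 and 1 for interferon genes, 2 and 1 for MHC class I, 0 and 1 for MHC class II and 2 and 1 for immediate early genes. The HOXA9 progenitor list ran from -0.07 to 0.12 and from 0.02 to 0.13, and T and NK markers from -0.04 to 0.36 and from -0.61 to 0.64, with 0 and 1 and 0 and 2 medians outside. In U937 the B-cell, megakaryocyte and erythroid lists ran from -0.08 to 0.23, -0.21 to 0.05 and -0.11 to 0.15. The single measured U937 mast cell gene, TPSAB1, was at 12.8, 28.0 and 29.5 FPKM, and the single eosinophil gene, CCR3, at 0.725, 1.56 and 1.80. The ratio of TPSAB1 was outside the random lists for 2 pairs and at 2-fold for 2 pairs, and that of CCR3 for 0. In the mouse line Epor, of the erythroid list, was at 1.25, 1.69 and 2.23 FPKM, and Pecam1, of the nonhematopoietic list, at 78.6, 87.3 and 88.7. ERCC spike-ins had 0 rows, and the nonhematopoietic list had 0 measured members in U937.

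The first pattern was that genes near DHODH differed strongly between libraries, in blocks of neighbours with different profiles. Within 2 Mb, 12 mouse genes and 6 U937 genes were alone in their locus. The lower quartile of their log2 span over the libraries was at least 2.17 in both lines. This argues against division of reads among overlapping genes for those genes only. They lie in stretches already seen to differ, and the test was chosen after that. A GC content or transcript length trend is argued against in the mouse line, since the largest trend removed was 0.08 and the removal left a median span of 3.24 within 1 Mb, and it could not be tried in U937. Adjacent genes within 5 Mb had profiles more alike than in any of 1000 shuffles of gene order (0 as alike in either line). This decides nothing, because the stretches had been found by a scan of neighbouring genes. Steps in DNA copy number along the chromosome and regulation of whole domains both stay open as hypotheses, and no DNA was measured.

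The second pattern was that mouse histone mRNAs were higher in q3 than in q2. A larger share of cells in S phase stays open. The highest ratio in the cell cycle list was 0.32, under 0.68, which is 50% of the histone median. That bar was set after the list median of -0.02 had been seen, and the list covers all phases, so the comparison does not decide it. A shift of the whole chromosome 13 cluster segment is argued against, because 6 other genes between its first and last histone gene had a median of -0.19 and 2 histone genes on other chromosomes had a median of 1.28. Carry-over of RNA without a poly-A tail stays open: Rn7sk, Rmrp and Rpph1 had a median ratio of 0.42, with Rpph1 at 10.3 FPKM in q2 and 5.21 in q3. Short RNA genes held 8.25%, 3.74% and 0.891% of the summed FPKM in q1, q2 and q3. The q3 share leaves out short RNAs found only in q3, so it can be too low and decides nothing here. From q1 to q3 Rn7sk, Rmrp and Rpph1 were all lower (7.05 to 4.35, 3.82 to 2.19 and 5.89 to 5.21 FPKM). The histone median was 0.49 for that pair, which goes against carry-over. With 3 weakly expressed RNAs of mixed direction this does not decide it.

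The third pattern was the lower level of mouse chromosome 13 in library q3. After the GC content and length trend was removed, the chromosome stayed below the others by at least 0.34 (-0.34 for q3 over q2), which argues against that trend as the cause. Its genes were split along the chromosome into 4 equal parts, each lower in q3 than in q1 and q2, with the highest median at -0.29, which is consistent with fewer copies of the whole chromosome in that library's cells. This may hold in all of those cells or part of them, and it remains a hypothesis without DNA data.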
